A study of Homo sapiens with 26 samples.

How the data were processed

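RNA sequencing was carried out on 26 pieces of human lung tissue, 8 areas from 3 healthy controls, 10 normal-appearing areas from 3 patients with idiopathic pulmonary fibrosis (IPF) and 8 scarred areas from the same 3 patients. Idiopathic pulmonary fibrosis is a progressive scarring disease of the lung. Per the labels' protocols, total RNA was extracted with TRIzol and made into libraries with an Illumina kit on an automated bead-based system. HTSeq 0.6.1p2 and the human genome build hg19 (GRCh37) are named in the submitters' processing notes. The aligner, the gene annotation and the strand setting of the counting are not given in the sources used here.

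The deposited values are raw counts, whole numbers of reads per gene symbol and library, for 23682 genes. All 26 columns were matched to samples through the library names in the labels, and 0 columns were left unmapped. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart. Near-identical genes share reads, so values of HBA1 and HBA2, SFTPA1, TPSAB1 and TPSB2, SERPINB3, KRT6A, KRT14, FCGR3B, CXCR1, CHIA and its pseudogene CHIAP2 are uncertain to that extent. Gene names were taken as deposited, and 20900 of them matched symbols in a RefSeq table of the GRCh38.p14 assembly. That table belongs to another build, so no coordinates are given. A set of 111 sex-linked genes was removed before every step, which left 23571 genes. HLA genes, genes of known germline copy number variation and rearranged receptor segments are not named.

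Library totals ranged from 4.69 to 12.1 M counts. A count of 0 in a library allows up to 3 counts, and such limits cover counting error only, since amplified reads are not independent molecules. The 28 pairs of areas from 1 donor and group differed by more than sampling noise, with a chi-square per degree of freedom of 4.5 to 52.5, and 0 pairs were identical, so each area was kept as a separate library.

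Areas of 1 donor are not independent. The 2 comparisons with healthy lung therefore used counts summed per donor, 3 against 3, in edgeR 4.0.16 (quasi-likelihood test with robust estimation, TMM scaling, genes kept by filterByExpr). Healthy controls and patients are different people, so their numbers do not pair. Scarred and normal-appearing areas come from the same patients according to the labels, and this comparison was fitted per area with the patient as a block. Its p-values measure the spread between areas of these 3 patients, not the spread between patients. P-values were adjusted by the Benjamini-Hochberg method, and genes under 0.05 were called. Standard errors are the absolute log2 fold change divided by the square root of the quasi-likelihood F. Expression is given in TMM-scaled CPM, a gene's share of the scaled library, as mean ± SD over donors in the comparisons with healthy lung and over areas in the comparison within patients. R 4.3.3, limma 3.58.1 and DESeq2 1.42.0 were also used.

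Before the data were examined, 31 gene lists of lung cell types and fibrosis pathways were fixed, and 351 of their 362 genes are in the table. The list of 9 mitochondrially encoded genes has 0 members in the table, so 30 lists were tested. MUC5AC and MCEMP1 were not analysed here. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Camera compares a list with all other genes, while fry asks whether its genes move one way on balance. Named genes followed a rule fixed at the same time. It takes the 10 higher and 10 lower called genes of largest fold change with at least 5 CPM in 1 group. Donor values of the 2 groups must not overlap or, within patients, the sign must be the same in all 3 patients, and clone or locus names are left out. It also takes up to 3 called members of smallest p from each list or, where none was called, the 2 of highest expression. These list members need not meet the conditions on expression, overlap or sign. Genes chosen after their values were seen are marked as such.

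The tests were checked on simulated counts with known changes. For normal-appearing against healthy (17557 genes), 21% of 2-fold and 85% of 4-fold changes were recovered, and 7.83% of calls were false. For scarred against healthy (17307 genes), the shares were 17% and 80%, with 9.35% false, above the nominal 5 in 100. For scarred against normal-appearing (15305 genes), they were 90% and 97%, with 3.11% false. The simulated areas were drawn independently with no difference between patients, so these last shares do not cover variation between patients. No recovered change had the wrong sign.

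Alternatives fixed before the data were examined included RLE scaling, library size only, DESeq2, 2 other filters on low counts, a random donor effect over all areas, and areas as independent replicates. They also included limma on mean log CPM per donor, 1 fit of all donor sums, fits without the patient block or on sums per patient, and leaving out each donor. The library numbers in the labels fall into 2 series. The smaller one holds 5 libraries, 1 healthy, 1 normal-appearing and 3 scarred, and was treated as a possible batch, left out or entered as a covariate.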

Results

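The data are read counts per gene from 26 lung areas, 8 from 3 healthy controls, 10 normal-appearing areas from 3 patients with idiopathic pulmonary fibrosis (IPF) and 8 scarred areas from the same patients. Donors gave between 1 and 4 areas to a group. Library totals were 4.69 to 9.77 M counts in healthy lung, 5.43 to 12.1 M in normal-appearing areas and 6.25 to 8.29 M in scarred areas. The 10 most counted genes of a library took 14.2% ± 2.61 of its counts in healthy lung (SD, n = 8 areas), against 10.3% ± 1.43 in normal-appearing (n = 10) and 10.2% ± 1.06 in scarred areas (n = 8). The consensus correlation of areas of 1 donor was 0.571 in healthy lung, compared with 0.154 in normal-appearing and 0.255 in scarred areas. It weighs likeness within a donor against differences between donors of the group. A higher value can therefore come from donors that differ more, and does not show that healthy areas of 1 donor were more alike. The 3 comparisons ask how normal-appearing tissue of a fibrotic lung differs from healthy lung, how scarred tissue differs from healthy lung, and how both kinds of tissue differ within a patient.

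**Figure D1:**
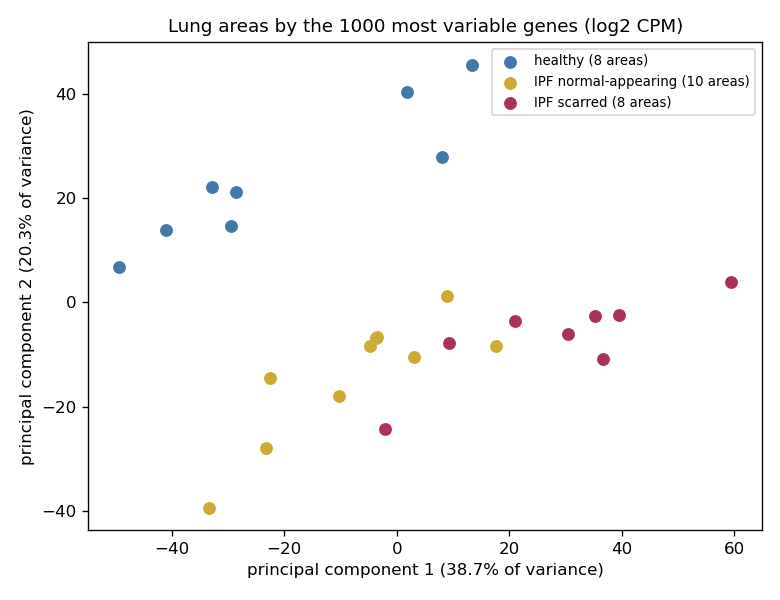
Principal components 1 and 2 of log2 CPM over the 1000 most variable genes, 1 point per lung area, coloured by group. The axes hold 38.7% and 20.3% of the variance, and scarred areas lie between -2.082 and 59.45 on component 1.

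In normal-appearing IPF areas, some genes of the fibrotic matrix and of lymphoid recruitment rose against healthy lung. APLNR, the apelin receptor, rose most, from 1.95 ± 0.993 to 65.9 ± 6.68 CPM (SD, n = 3 donors each), a log2 fold change of 5.04 ± 0.36 (SE, edgeR adjusted p = 0.00828). The chemokine CCL19, which attracts lymphocytes and dendritic cells through CCR7, rose from 2.15 ± 1.14 to 37.0 ± 9.74 CPM (log2 fold change 4.07 ± 0.44). COL10A1, a type X collagen chain, rose from 2.34 ± 0.883 to 27.4 ± 9.24 CPM (3.53 ± 0.38), and granulysin (GNLY), a cytotoxic granule protein, from 13.3 ± 4.39 to 136 ± 71.6 CPM (3.35 ± 0.50). IL1R2, a decoy receptor for interleukin-1, fell from 74.6 ± 14.99 to 8.74 ± 1.73 CPM, with a log2 fold change of -3.10 ± 0.22 (edgeR adjusted p = 0.00828).

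The other genes of largest increase were the tight junction gene CLDN2 (log2 fold change 4.58), the chemokine CXCL14 (4.02), RGS4 (3.76), LAMP5 (3.76), the thyroid hormone deiodinase DIO2 (3.35) and the matrix gene MXRA5 (3.14). Those of largest decrease were WFDC12 (-4.55), GPIHBP1 (-3.51), which anchors lipoprotein lipase on capillaries, and CHIA (-3.39), an acidic chitinase. AZGP1 (-3.39), FMO5 (-3.32), the metalloproteinase inhibitor TIMP4 (-2.97), the lipid droplet gene PLIN5 (-2.36), HSD17B6 (-2.36) and BTNL9 (-2.32) also fell.

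All 24 genes of the fibrillar collagen and matrix list had positive fold changes, with a median log2 fold change of 1.82. Of these, 6 rose over all genes tested and 19 adjusted over the list alone, among them COL15A1 (2.53 ± 0.28) and ASPN (2.67 ± 0.35). The limma camera adjusted p was 1.87e-19, and the adjusted p was 0.197 with an estimated correlation. Among metalloproteinases, 2 of 13 rose, also 2 adjusted over the list alone. They were MMP11 (3.59 ± 0.59) and the gelatinase MMP2 (1.21 ± 0.21), with a camera adjusted p of 0.00107, and an adjusted p of 0.264 with an estimated correlation. MMP11 had a mean under 5 CPM in both groups, so its fold depends on few counts. In the TGF-beta list, all 13 fold changes were positive and 1 gene, LTBP2, rose (1.93 ± 0.29, 6 adjusted over the list alone). Its camera adjusted p was 5.27e-06, and the adjusted p was 0.243 with an estimated correlation. No smooth muscle gene was called over all genes and 4 of 10 were adjusted over the list alone, with ACTA2 at 729 ± 374 and 1692 ± 258 CPM (camera adjusted p = 1.84e-05, limma). With an estimated correlation the adjusted p was 0.364. In the senescence list, IGFBP7 rose (1.5 ± 0.17), 1 of 10 over all genes and 2 adjusted over the list alone (camera adjusted p = 0.00563, limma). An estimated correlation gave an adjusted p of 0.264.

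Cytotoxic, T cell and lymphoid chemokine lists all had positive fold changes for every tested member. In the NK and cytotoxic list, with a median of 2.36, GNLY and the granzyme GZMA (2.36 ± 0.32) rose, 2 of 9 over all genes and 9 adjusted over the list alone. Camera gave an adjusted p of 4.66e-11 in limma, and the adjusted p was 0.243 with an estimated correlation. The T cell list had a median of 1.59, with 0 of 13 called over all genes and 10 adjusted over the list alone. CD2 had 14.4 ± 6.91 CPM in healthy and 42.5 ± 21.8 CPM in normal-appearing tissue (camera adjusted p = 1e-09, limma). Its adjusted p was 0.264 with an estimated correlation. In the lymphoid chemokine list, with a median of 2.39, CCL19 and CCL5 (2.30 ± 0.39) rose, 2 of 10 over all genes and 8 adjusted over the list alone. Its camera adjusted p was 9.84e-10 in limma, and the adjusted p was 0.197 with an estimated correlation. B cell genes (median 1.12) had 0 of 9 called over all genes and 5 adjusted over the list alone, plasma cell genes (1.04) 0 of 8 by both counts, and interferon-stimulated genes (0.555) 0 of 12 and 3 adjusted over the list alone. Camera adjusted p-values were 0.000545, 0.000293 and 1.84e-05 in limma. The adjusted p-values were 0.254, 0.314 and 0.344 with an estimated correlation.

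The red blood cell gene HBB had 67.6 ± 77.1 CPM in healthy and 415 ± 214 CPM in normal-appearing tissue, a log2 fold change of 2.62 ± 0.93 that was not called (edgeR adjusted p = 0.277). The list of red blood cell genes had 0 of 7 called over all genes and 0 adjusted over the list alone (camera adjusted p = 0.0270, limma). This call was lost with an estimated correlation (adjusted p = 0.587). Of monocyte and neutrophil genes, 1 of 10 fell, also 1 adjusted over the list alone. It was CSF3R, the receptor of granulocyte colony-stimulating factor (-1.19 ± 0.19), while the list's median was 0.165 and its mean -0.249 (camera adjusted p = 0.602, limma).

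All 12 alveolar type 2 genes, markers of the cells that make surfactant, had negative fold changes, with a median of -0.872. PGC, a pepsinogen, fell (-1.55 ± 0.19), 1 of 12 over all genes and 4 adjusted over the list alone (camera adjusted p = 7e-05, limma). Under an estimated correlation it did not pass (adjusted p = 0.264). The epithelial immunoglobulin transporter PIGR fell (-1.83 ± 0.25), 1 of 14 secretory genes over all genes and also 1 adjusted over the list alone (camera adjusted p = 0.851, limma). Cytosolic ribosomal protein genes had 19 of 19 negative fold changes with a median of -0.271, and 0 were called over all genes or adjusted over the list alone (camera adjusted p = 2.65e-06, limma). It had an adjusted p of 0.364 with an estimated correlation.

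Inflammatory cytokine genes had 0 of 14 called over all genes and 3 adjusted over the list alone, with CCL2 at 156 ± 199 and 500 ± 189 CPM (camera adjusted p = 0.00136, limma). Estimating the correlation gave an adjusted p of 0.517. Lymphatic endothelium and profibrotic macrophage genes each had 0 called over all genes and 2 adjusted over the list alone, with CCL21 at 101 ± 25.2 and 266 ± 67.5 CPM, and cartilage genes had 0 of 8 by both counts. Camera adjusted p-values were 0.0430, 0.0430 and 0.0312 in limma. The adjusted p-values were 0.423, 0.517 and 0.314 with an estimated correlation. The other lists did not pass camera, and in 6 of 30 lists median, mean and camera differed in sign, such as basal genes with a median of -1.21 and a direction of up. Areas of 1 healthy donor had basal scores (mean log2 CPM of the list's genes) of 2.72 to 5.36. The other healthy areas had -0.229 to 0.369 and scarred areas 2.81 to 5.55.

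In all, 178 of 17853 genes were called, 105 higher and 73 lower, and 2421 had an unadjusted p under 0.05. With library size as the only scaling, 71.8% of calls were higher, against 59% with TMM. Leaving out 1 donor at a time left between 6 and 229 genes, DESeq2 called 1089, and 18 of 30 lists passed camera, against 0 with an estimated correlation and 1 with fry.

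In scarred areas, some B cell, lymphoid chemokine, matrix and metalloproteinase genes rose against healthy lung, and some alveolar type 2 genes and the capillary gene CA4 fell. MS4A1, which encodes the B cell antigen CD20, rose from 4.97 ± 1.34 to 56.5 ± 19.5 CPM (SD, n = 3 donors each), a log2 fold change of 3.50 ± 0.34 (edgeR adjusted p = 0.0159). CXCL13, a chemokine that attracts B cells, rose from 0.818 ± 0.430 to 25.9 ± 6.62 CPM (4.97 ± 0.46). The matrix metalloproteinase MMP7 rose from 17.2 ± 12.1 to 320 ± 173 CPM (4.22 ± 0.69), and the macrophage chemokine CCL18 from 69.4 ± 20.9 to 436 ± 95.8 CPM (2.65 ± 0.28). CA4, a carbonic anhydrase of lung capillaries, fell from 65.2 ± 16.6 to 6.23 ± 3.12 CPM, with a log2 fold change of -3.41 ± 0.44 (edgeR adjusted p = 0.0259).

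The largest increases were those of IGFL2 (log2 fold change 5.86) and transthyretin, TTR (5.75). They had 7 and 9 counts over all healthy areas against 415 and 550 over all scarred areas, so their folds depend on few counts. CLDN2 (5.47), APLNR (5.01), KRT14 (4.42), CXCL14 (4.42), MMP11 (4.27), DIO2 (4.23) and the B cell gene FCRLA (4.22) followed. KRT14 and FCRLA also rest on few counts, 17 and 20 over all healthy areas against 478 and 413 over all scarred areas. Besides CA4, CHIAP2 (-4.87), WFDC12 (-4.72), CHIA (-3.48), IL1R2 (-3.25), CLEC4E (-3.21), TIMP4 (-3.17), FMO5 (-3.06), HIF3A (-2.98) and CBS (-2.83) fell.

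Of the 24 matrix genes, 10 rose over all genes and 19 adjusted over the list alone, with a median of 1.92, including COL15A1 (2.85 ± 0.27), COL10A1 (3.28 ± 0.35) and COL6A3 (2.20 ± 0.26). The camera adjusted p was 1.45e-19 in limma, and the adjusted p was 0.166 with an estimated correlation. Of 13 metalloproteinase and inhibitor genes, MMP7, MMP11 and MMP2 (1.37 ± 0.22) rose, with 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00015, limma). With an estimated correlation the adjusted p was 0.168. Of 10 B cell genes, 4 rose over all genes and 7 adjusted over the list alone, among them CD79A (3.41 ± 0.39), a part of the B cell receptor complex (camera adjusted p = 5.08e-08, limma). An estimated correlation gave an adjusted p of 0.109. Plasma cell genes had a median of 2.39, and SDC1 rose (0.95 ± 0.16), 1 of 8 over all genes and 8 adjusted over the list alone (camera adjusted p = 1.79e-07, limma). Its adjusted p was 0.206 with an estimated correlation. In the lymphoid chemokine list 5 of 10 rose and 8 adjusted over the list alone, with CCL19 at 4.21 ± 0.43 and CCR7 at 2.88 ± 0.48 (camera adjusted p = 4.58e-09, limma). This call was lost with an estimated correlation (adjusted p = 0.168). T cell genes had 0 of 13 called over all genes and 8 adjusted over the list alone, with a median of 1.45. NK and cytotoxic genes had GZMA called (2.07 ± 0.33), 1 of 9 over all genes and 5 adjusted over the list alone. Their camera adjusted p-values were 2.92e-06 and 5.45e-05 in limma, and both adjusted p-values were 0.336 with an estimated correlation.

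All 12 type 2 genes had negative fold changes with a median of -1.07, and 3 fell over all genes and 5 adjusted over the list alone. These 3 were the surfactant protein gene SFTPA1 (-1.24 ± 0.20), LAMP3 (-1.56 ± 0.24) and PGC (-1.31 ± 0.23), with a camera adjusted p of 9.96e-06 in limma. Under an estimated correlation it did not pass (adjusted p = 0.174). All 10 type 1 genes had negative fold changes with a median of -1.02, and 0 were called over all genes and 4 adjusted over the list alone. Their mean log2 CPM overlapped between groups, from 6.24 to 8.56 in healthy and from 5.28 to 7.15 in scarred areas, with 3 of 8 healthy areas, all of 1 donor, inside the scarred range. CAV1, caveolin-1, had 1328 ± 576 CPM in healthy and 620 ± 51.9 CPM in scarred tissue (camera adjusted p = 9.96e-06, limma). It had an adjusted p of 0.336 with an estimated correlation. Of 12 vessel endothelium genes CA4 fell, 1 over all genes and 5 adjusted over the list alone, with a list median of -0.741 (camera adjusted p = 8.73e-05, limma). Estimating the correlation gave an adjusted p of 0.336. CSF3R also fell (-1.65 ± 0.22), 1 of 10 monocyte and neutrophil genes over all genes and 3 adjusted over the list alone (camera adjusted p = 0.00576, limma). With an estimated correlation the adjusted p was 0.459.

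Airway lists had positive medians, 1.21 for basal, 1.56 for secretory and 1.47 for ciliated genes. Of these, KRT14 rose, 1 of 12 basal genes over all genes and also 1 adjusted over the list alone, and 0 of 14 secretory and 0 of 15 ciliated genes were called by either count. Camera adjusted p-values were 0.00015, 0.000738 and 5.45e-05 in limma. The adjusted p-values were 0.459, 0.514 and 0.483 with an estimated correlation. The spread between donors was wide, with BPIFB1 at 248 ± 398 CPM in healthy and 3205 ± 3641 CPM in scarred tissue. The healthy donor with high basal scores also had secretory scores of 6.47 to 7.33, against 3.58 to 4.72 in the other healthy areas and 5.36 to 9.01 in scarred areas. Its libraries held 0.522% to 0.683% of counts in the ribosomal RNA gene RNA45S5, against 0.209% to 0.396% in the other healthy libraries.

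In the TGF-beta list LTBP2 rose (1.47 ± 0.25), 1 of 13 over all genes and 3 adjusted over the list alone (camera adjusted p = 0.00750, limma), and in the senescence list IGFBP7 rose (1.53 ± 0.25), 1 of 10 and also 1 adjusted over the list alone (0.0242). Both adjusted p-values were 0.336 with an estimated correlation. CCL18 was the 1 of 10 profibrotic macrophage genes that rose, with 2 adjusted over the list alone (camera adjusted p = 0.00108, limma). An estimated correlation gave an adjusted p of 0.206. Smooth muscle, Wnt and cell cycle genes had 0 called over all genes, and 3, 2 and 0 adjusted over the list alone, with camera adjusted p-values of 5.45e-05, 0.0465 and 0.0449 in limma. The adjusted p-values were 0.336, 0.336 and 0.578 with an estimated correlation. CCL21 rose (1.49 ± 0.21), 1 of 6 lymphatic genes, with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.429, limma). The other lists did not pass camera. Inflammatory genes had a median of -0.964 with a camera direction of up (adjusted p = 0.867, limma).

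Altogether 236 of 17617 genes were called, 138 higher and 98 lower, with 2831 at an unadjusted p under 0.05. Leaving out 1 donor at a time left 9 to 129 genes and leaving out the smaller library number series, which removes all scarred tissue of 1 patient, left 149, while DESeq2 called 1331. Camera passed 20 of 30 lists, against 0 with an estimated correlation and 5 with fry.

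Both comparisons use the same healthy donors and the same patients. Of 17475 genes tested in both, 63 were higher and 42 lower in both, and 0 were called in opposite directions. Independent lists of these sizes would share 0.805 higher and 0.409 lower genes. Simulated unchanged groups against the same controls shared a median of 0 genes. With no group effect few genes can be called there, so this gives no chance value for the overlap of called genes. Across genes, which are not independent replicates, fold changes correlated with r = 0.755 and a covariance of 0.307. Simulation with shared controls gave r = 0.505 and a covariance of 0.0857, and with patients also shared r = 0.605 and a covariance of 0.103. The difference in covariance was 0.221 and 0.204. With 3 controls no split leaves 2 in each part, so some of the excess may come from the shared controls.

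**Figure D2:**
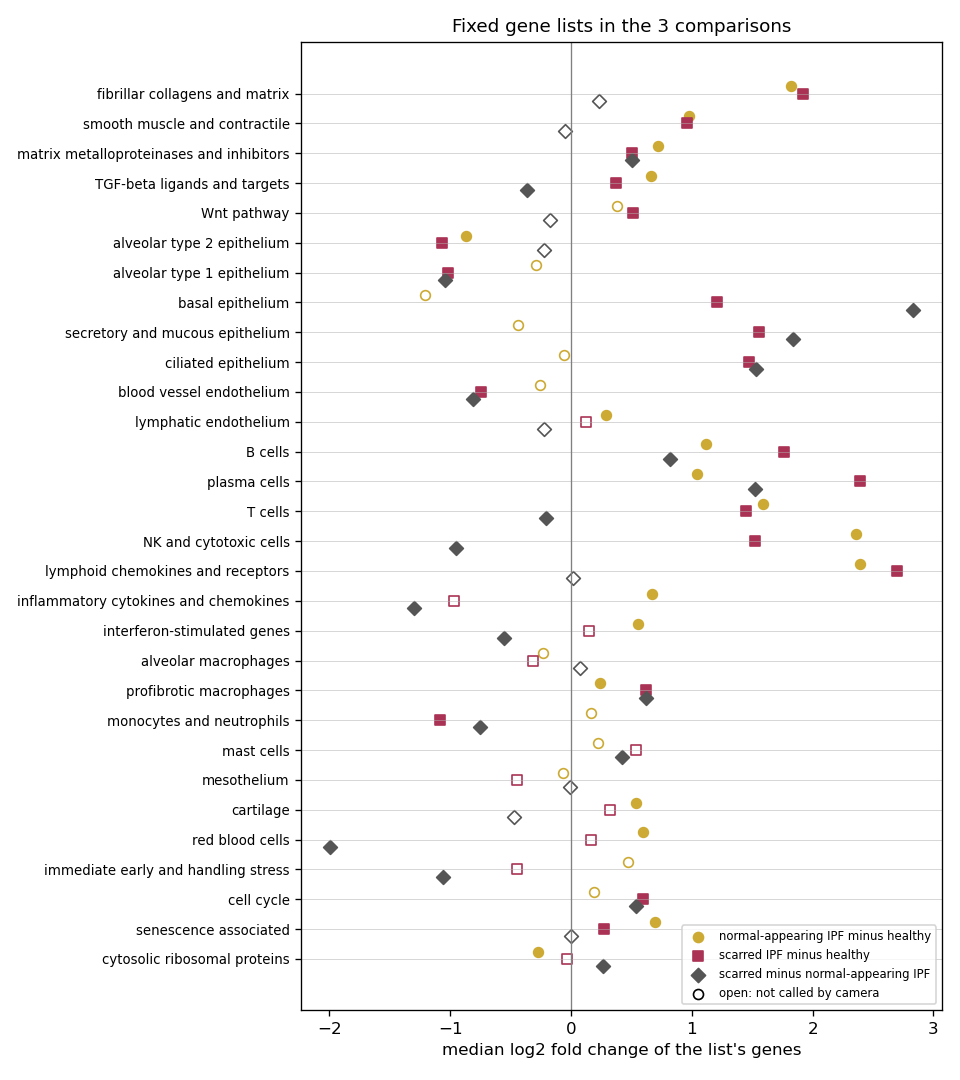
Median log2 fold change (x axis) of the genes of each of 30 fixed lists (y axis) in the 3 comparisons, marked by shape and colour; filled points passed limma's camera at a preset correlation. Basal genes lie at 2.83 and inflammatory genes at -1.3 in scarred minus normal-appearing areas; with an estimated correlation 0 lists passed in any comparison.

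Within patients, most basal, secretory and B lineage genes and some metalloproteinase genes rose in scarred areas, and most type 1 alveolar, vessel endothelium and inflammatory genes fell. KRT5, a keratin of airway basal cells, rose from 2.36 ± 3.76 to 30.3 ± 24.6 CPM (SD, n = 10 and 8 areas), a log2 fold change of 4.04 ± 0.77 (edgeR adjusted p = 0.00341). MMP7 rose from 74.2 ± 35.8 to 372 ± 178 CPM (2.66 ± 0.33), and SCGB3A2, a secretoglobin of small airways, from 230 ± 104 to 719 ± 238 CPM (1.60 ± 0.22). CAV1 fell from 1222 ± 316 to 627 ± 149 CPM (-1 ± 0.17), and the cytokine IL6 from 146 ± 133 to 23.3 ± 21.1 CPM, a log2 fold change of -2.56 ± 0.56 (edgeR adjusted p = 0.00745).

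The genes of largest increase also included the airway defence proteins BPIFA1 (log2 fold change 4.76) and BPIFB1 (4.43), LY6D (4.20), KRT6A (4.10), KRT15 (3.70), the collagenase MMP1 (3.70), MIR205HG (3.69), MSMB (3.54) and S100A2 (3.42). Those of largest decrease were MFAP5 (-3.23), ITLN2 (-3.18), CSF3 (-2.80), the serotonin transporter SLC6A4 (-2.63), CLEC4M (-2.52), AGER (-2.37), IL1RL1 (-2.34), SLC14A1 (-2.14) and CA4 (-2.12).

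**Figure D3:**
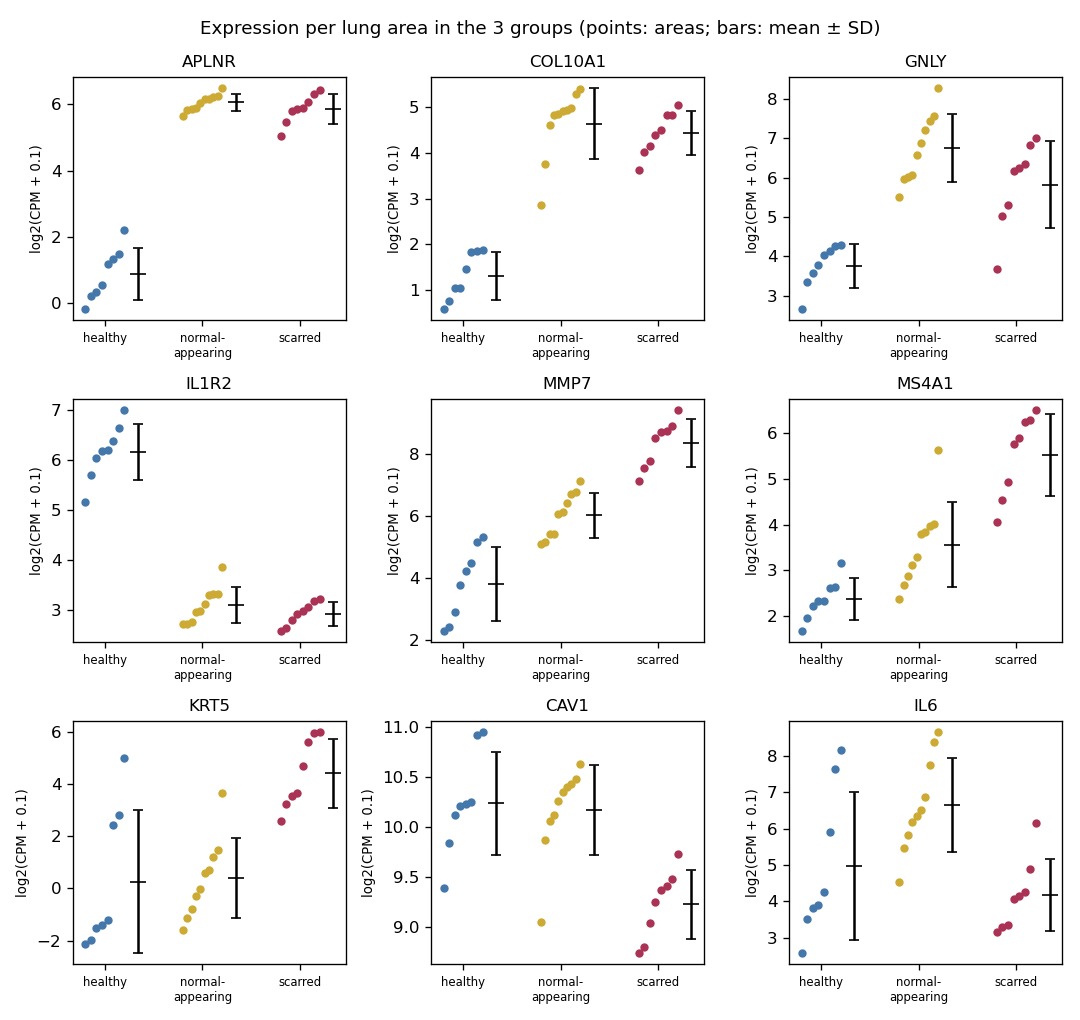
Expression per lung area, as log2 of CPM plus 0.1, of 9 genes named in the text in healthy, normal-appearing and scarred areas; points are areas in ascending order within a group and bars the mean and SD over areas. MMP7 has a mean of 74.2 CPM in normal-appearing and 372 CPM in scarred areas.

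Of 12 basal genes, 9 rose over all genes and 12 adjusted over the list alone, with a median of 2.83 and TP63, the basal cell transcription factor, at 1.74 ± 0.33 (camera adjusted p = 2.85e-10, limma). Its adjusted p was 0.111 with an estimated correlation. Of 14 secretory genes, 12 rose and 13 adjusted over the list alone, with LTF, lactoferrin, at 2.63 ± 0.50 and AGR2 at 1.21 ± 0.24 (camera adjusted p = 1.07e-10, limma). This call was lost with an estimated correlation (adjusted p = 0.111). The sign of AGR2 was not the same in all 3 patients. Ciliated genes had 0 of 15 called over all genes and 14 adjusted over the list alone, with a median of 1.53 and C20orf85 at 37.0 ± 29.5 and 153 ± 96.5 CPM (camera adjusted p = 4.23e-07, limma). Under an estimated correlation it did not pass (adjusted p = 0.222). Of 5 cartilage genes, 2 fell, also 2 adjusted over the list alone, MATN3 (-1.21 ± 0.27) and HAPLN1 (-1.12 ± 0.25), with a camera adjusted p of 0.0933 in limma.

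Type 1 alveolar genes fell in 9 of 10 cases over all genes and 10 adjusted over the list alone, with RTKN2 at -2.40 ± 0.45 (camera adjusted p = 1.02e-08, limma). It had an adjusted p of 0.111 with an estimated correlation. Type 2 genes had 0 of 12 called by either count, with SFTPB at 19230 ± 7385 and 19080 ± 4314 CPM (camera adjusted p = 0.196, limma). Of 12 vessel endothelium genes, 7 fell and 8 adjusted over the list alone, among them EMCN (-0.82 ± 0.12), EDNRB (-0.87 ± 0.13) and PECAM1 (-0.65 ± 0.11), with a camera adjusted p of 3.23e-07 in limma. Estimating the correlation gave an adjusted p of 0.111. The lymphatic marker LYVE1 (-1.55 ± 0.24) and the mesothelial gene UPK3B (-2.61 ± 0.50) fell, each 1 of 6 in its list by both counts (camera adjusted p = 0.326 and 0.328, limma).

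In the B cell list 6 of 9 rose and 7 adjusted over the list alone, with MS4A1 at 2.00 ± 0.36 and CD22 at 0.82 ± 0.15 (camera adjusted p = 3.2e-06, limma). All 8 plasma cell genes rose by both counts, 8 adjusted over the list alone, with DERL3 at 1.73 ± 0.35, FCRL5 at 1.72 ± 0.37 and POU2AF1 at 1.57 ± 0.36 (camera adjusted p = 1.28e-07, limma). Both adjusted p-values were 0.111 with an estimated correlation. NK and cytotoxic genes fell in 7 of 9 cases, also 7 adjusted over the list alone beside 1 higher, with KLRD1 at -0.97 ± 0.20, FGFBP2 at -1.42 ± 0.29 and KLRF1 at -1.09 ± 0.24 (camera adjusted p = 1.96e-05, limma). With an estimated correlation the adjusted p was 0.131. CD5 fell (-0.62 ± 0.14), without the same sign in all 3 patients. It was 1 of 13 T cell genes by both counts, also 1 adjusted over the list alone (camera adjusted p = 0.0486, limma). An estimated correlation gave an adjusted p of 0.463, and without 1 patient the T cell list turned direction and did not pass (camera adjusted p = 0.93, limma). In the lymphoid chemokine list CXCL13 (2.76 ± 0.42) and CXCR5 (1.56 ± 0.34) rose and 3 genes fell, CXCL10 among them (-0.95 ± 0.19). With 3 higher and 3 lower adjusted over the list alone, the median was 0.0141 and camera's direction was down (adjusted p = 0.928, limma).

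Inflammatory cytokine genes fell in 10 of 14 cases and 12 adjusted over the list alone, with PTGS2 at -1.97 ± 0.30, IL1B at -1.86 ± 0.33 and CCL4 at -0.91 ± 0.16 (camera adjusted p = 6.95e-10, limma). Interferon-stimulated genes fell in 9 of 12 and 10 adjusted over the list alone, with OAS2 at -0.79 ± 0.13, OAS3 at -0.59 ± 0.10 and RSAD2 at -1.13 ± 0.22 (camera adjusted p = 6.7e-09, limma). Immediate early genes fell in 7 of 11 and 10 adjusted over the list alone, with FOS at -1.74 ± 0.33, ZFP36 at -1.67 ± 0.31 and ATF3 at -1.61 ± 0.29 (camera adjusted p = 6.27e-08, limma). All 3 red blood cell genes fell, also 3 adjusted over the list alone, with HBB at -1.63 ± 0.26 (camera adjusted p = 5.38e-05, limma). The adjusted p was 0.111 for each of these 4 lists with an estimated correlation. Monocyte and neutrophil genes fell in 5 of 10 and 9 adjusted over the list alone, with FCGR3B at -1.64 ± 0.30, CXCR1 at -1.53 ± 0.30 and FCN1 at -1.18 ± 0.28 (camera adjusted p = 2.73e-06, limma). Its adjusted p was 0.143 with an estimated correlation.

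Among matrix genes COMP (1.07 ± 0.24), COL1A1 (1.07 ± 0.30) and COL6A3 (0.59 ± 0.18) rose, 3 of 24, with 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.120, limma). In the metalloproteinase list 4 of 12 rose and TIMP3 fell (-0.81 ± 0.14), with 5 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0415, limma). This call was lost with an estimated correlation (adjusted p = 0.169). Of 13 TGF-beta genes, 5 fell and 6 adjusted over the list alone beside 1 higher, with CTGF at -1.32 ± 0.22, the inhibitor SMAD7 at -0.70 ± 0.12 and TGFB2 at -0.63 ± 0.12 (camera adjusted p = 0.000287, limma). Under an estimated correlation it did not pass (adjusted p = 0.125). No smooth muscle gene was called, 0 of 10 by both counts (camera adjusted p = 0.702, limma). SFRP4, a Wnt antagonist, fell (-1.21 ± 0.28), 1 of 13 Wnt genes and also 1 adjusted over the list alone (camera adjusted p = 0.328, limma). CDKN2B (-1.26 ± 0.19) and CDKN1A (-0.75 ± 0.19), inhibitors of the cell cycle, fell, 2 of 10 senescence genes and also 2 adjusted over the list alone (camera adjusted p = 0.628, limma). For CDKN1A the sign was not the same in all 3 patients.

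In the profibrotic macrophage list SPP1 (1.93 ± 0.43), MMP12 (1.53 ± 0.37) and CCL18 (0.99 ± 0.30) rose, 3 of 10 and 5 adjusted over the list alone (camera adjusted p = 0.00398, limma). Mast cell genes HDC (0.66 ± 0.16) and MS4A2 (0.73 ± 0.19) rose, 2 of 6 and 3 adjusted over the list alone (camera adjusted p = 0.00918, limma). Both adjusted p-values were 0.221 with an estimated correlation. HDC did not have the same sign in all 3 patients. Of 11 alveolar macrophage genes INHBA fell (-0.69 ± 0.22), with 0 adjusted over the list alone (camera adjusted p = 0.771, limma). The alveolar macrophage list depended on the patients, with medians of -0.527 to 0.569 without 1 of them, and passed camera in 2 of 3 such fits in opposite directions (adjusted p = 5.12e-05 for the upward one, limma). Cell cycle genes rose in 7 of 12 and 9 adjusted over the list alone, with TOP2A at 0.74 ± 0.15, CENPF at 0.65 ± 0.14 and BIRC5 at 0.82 ± 0.18 (camera adjusted p = 3.25e-06, limma). It had an adjusted p of 0.111 with an estimated correlation. Cytosolic ribosomal protein genes rose in 11 of 19 and 16 adjusted over the list alone, by a median of 0.263, with RPS24 at 0.42 ± 0.09, RPL34 at 0.35 ± 0.08 and RPL10A at 0.35 ± 0.09 (camera adjusted p = 1.33e-08, limma). Estimating the correlation gave an adjusted p of 0.169.

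In this comparison 2184 of 15419 genes were called by edgeR, 1000 higher and 1184 lower, with 276 higher and 238 lower by more than 2-fold. Of the 2184, 1668 had the same sign in all 3 patients. Which direction held more calls depended on the processing, with 1078 higher and 907 lower under library size only, 1324 and 1194 with a random donor effect, and 479 and 817 without the smaller library number series. On sums per patient with the patient as a replicate block, 3 pairs, edgeR called 0 genes, with 2033 at an unadjusted p under 0.05. Leaving out 1 patient at a time left 1, 7 or 3378 genes, the 3378 without the patient who gave 1 scarred area. That scarred area scored 6.244 on vessel endothelium, against 5.911 to 6.297 in the patient's normal-appearing areas. Its immediate early score, 6.245, lay above theirs, 5.756 to 5.89, against the fall over all patients. Its B cell score, 3.136, lay above theirs, 1.518 to 1.909, as in the other patients. The fit with no replicate block called 1431. The areas of the larger library number series alone, where only 2 patients have scarred tissue, gave 1296. The smaller series was too small to test by itself.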

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

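Mean scores of 30 lists (mean log2 CPM of a list's genes) and library totals were compared among the areas of each group, 93 sets of 8 or 10 areas, by the gap of the highest or lowest area to its nearest neighbour. This measure was chosen after the data were examined. In 11 sets 1 area stood apart by more than Dixon's critical value, where chance gives about 4.6, and areas of 1 donor are not independent.

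In scarred tissue the lowest alveolar type 2 score was 7.89, against 9.33 in the next area, the lowest alveolar macrophage score was 5.08, against 6.42, and the lowest mesothelium score was 1.59, against 2.35. These 3 values came from 1 area, which also had the lowest type 1 and the highest secretory score in scarred tissue, so they are not separate findings. The highest T cell score in scarred tissue was 4.45, against 3.33 in the next area, and the highest cartilage score was 2.46, against 1.61. The T cell value came from the only scarred area of 1 patient. Normal-appearing areas of that patient scored 4.16 to 4.52, against 2.96 to 3.58 in the other patients, so the value follows the patient. The largest scarred library held 8.29 M counts, against 7.18 M in the next.

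In normal-appearing tissue the highest basal score was 3.89, against 2.22 in the next area, and the highest metalloproteinase score was 5.48, against 4.68, both in 1 area. The highest B cell score was 2.78, against 2.03, and the highest ribosomal protein score was 9.19, against 9. The lowest mast cell score was 4.63, against 5.05.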

How the results depend on the processing

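The alternatives below were fixed before the data were examined. RLE scaling, both other filters and library size only kept all 3 counts of called genes within 1.5 times, but library size only gave a median log2 fold change of all genes of 0.13 in scarred against healthy, against 0.011 with TMM, and raised the share of higher calls from 59% to 71.8% in normal-appearing against healthy. The named called genes reversed under 0 alternatives, yet 27 of 31, 36 of 39 and 84 of 84 in the 3 comparisons lost their call under at least 1, and 3, 4 and 5 did so under another scaling, filter or tool.

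For normal-appearing against healthy, 178 genes became 1089 with DESeq2, 1635 with a random donor effect, 3182 with the donor ignored, 298 with limma on mean log CPM and 318 in 1 fit of all donor sums, and 6 to 229 without 1 donor. For scarred against healthy, 236 became 1331 with DESeq2, 2246 with a random donor effect, 4242 with the donor ignored, 682 in 1 fit of all donor sums, 149 without the smaller library number series (which removes all scarred tissue of 1 patient), and 9 to 129 without 1 donor. Ignoring the donor counts areas of 1 person as independent. For scarred against normal-appearing, 2184 became 1296 without that series, with 2 patients left to compare, 1431 with no replicate block, 0 on sums per patient with the replicate block (edgeR, 2033 at an unadjusted p under 0.05), and 1 to 3378 without 1 patient. With 3 pairs few degrees of freedom remain. Of the 2184, 1000 were higher and 1184 lower, a balance that turned to 1078 and 907 with library size only, 1324 and 1194 with a random donor effect and 734 and 697 with no replicate block, and went further to 479 and 817 without that series and 616 and 960 with it as a covariate. The cause was not tested for the other shifts.

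Camera's 18, 20 and 20 lists became 0, 0 and 0 with an estimated correlation, and the first 2 became 1 and 5 with fry. Without 1 donor camera called 17 to 23, 17 to 22 and 20 to 21 lists. The 105 genes shared by the comparisons with healthy became 325 at an adjusted p under 0.1. Without 1 donor, 3 lists turned direction among those that passed camera with all donors or without that donor, and the cause was not tested. Lists that passed in neither fit were not counted. Their medians could change sign too, such as that of type 2 genes in scarred against normal-appearing, -0.222 in all areas and up to 0.0352 without 1 patient. Inflammatory genes in scarred against healthy had a camera adjusted p of 0.0211 where they turned and 0.0039 to 0.837 over the donors left out (limma). In scarred against normal-appearing, alveolar macrophage genes had 5.12e-05 where they turned and 5.12e-05 to 0.841 in all, and T cell genes 0.93 and 0.00135 to 0.93. At this depth and with 3 donors, 21% and 17% of simulated 2-fold changes were recovered in the comparisons with healthy, so a gene that was not called may still differ.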

Other observations

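Families of genes were tested by symbol, chosen after the data were examined. The 42 collagen genes had a median log2 fold change of 0.575 in normal-appearing areas against healthy lung, and COL10A1, COL15A1 and COL14A1 rose (limma camera adjusted p = 8.32e-12, and 0.0209 with an estimated correlation). In scarred areas against healthy lung, 7 of 40 rose, led by COL1A1 (camera adjusted p = 7.83e-08, limma). The adjusted p was 0.421 with an estimated correlation. Within patients, 5 collagen genes rose and 4 fell in scarred areas, COL4A3 and COL4A4 among the called genes, with a family median of -0.00797 (camera adjusted p = 0.8, limma). Of 16 keratin genes, 7 rose within patients, and 1 of 17 semaphorin genes rose while 5 fell (camera adjusted p = 0.00224 and 0.019, limma). Both adjusted p-values were 0.435 with an estimated correlation.

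The tests below were chosen after the results were seen, except the 2 covariate tests of inflammatory genes and the test of glucocorticoid-induced genes, whose bounds were set before. For the counts of called genes, 10 splits of 6 donors are too few for a share under 0.05. The real split gave 178 genes in normal-appearing against healthy, with a highest other of 1, and 236 in scarred against healthy, with a highest other of 0, so 1 of 10 splits gave as many in each. Within patients, 1 of 100 splits, the real one, gave as many as 2184 genes, with a highest other of 0. That is the smallest share 100 splits can give, so chance is unlikely among these areas but not excluded. The splits treat areas of a patient as independent and do not cover the spread between patients.

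Cytotoxic and T cell genes had positive fold changes in normal-appearing areas against healthy lung, with 2 of 9 and 0 of 13 called and camera calls lost with an estimated correlation (adjusted p = 0.243 and 0.264, limma). With library size as the only scaling, removing the 10 most counted genes and the alveolar type 2 list took the median of all other genes from 0.0603 to 0.00659 and the NK and T cell median from 1.71 to 1.66, so a few abundant genes do not account for it. A lower share of type 2 cells would raise all other cell types, but the endothelium and alveolar macrophage medians reached at most 0.151. Blood left in the tissue cannot be told apart from the pattern. Monocyte and neutrophil genes, which blood would bring, had a median of 0.165, against 2.36 for NK genes, and at most 23.4% of the NK median without any 1 donor, but 6 were positive and 4 negative, from -2.45 to 1.4. Red blood cell genes went with blood, with HBB at a log2 fold change of 2.62 ± 0.93 that was not called (edgeR adjusted p = 0.277) and a list direction of up (camera adjusted p = 0.0270, limma). With an estimated correlation that list had an adjusted p of 0.587. Areas of 1 healthy donor argue against blood alone. Their red blood cell scores, 2.87 to 4.14, lay within those of normal-appearing areas, 2.41 to 5.22. Their NK scores were 2.30 to 2.58, against 4.09 to 5.59 in normal-appearing areas. With only 1 such donor, blood stays open as a cause. All healthy tissue comes from people without the disease, so differences in tissue source and handling cannot be separated from disease, and more lymphocytes in normal-appearing areas remain a hypothesis.

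Of basal and secretory genes, 9 of 12 and 12 of 14 rose in scarred against normal-appearing areas, though both lists lost camera's call with an estimated correlation (adjusted p = 0.111 for each, limma). Cartilaginous bronchus in the tissue blocks would bring cartilage transcripts, but 0 of 8 scarred areas stood above every normal-appearing area on at least 3 of 6 cartilage-specific genes. Of 21 called basal and secretory genes, 18 stayed called with the library number series as a covariate. Without the smaller series 18 also stayed called, but that fit has scarred tissue of only 2 patients. The remaining patient's only scarred area is in the smaller series, and the normal-appearing areas are all in the larger series. There the covariate fit, which keeps all 3 patients, cannot separate series from appearance. Both fits therefore argue against the series as the cause in the same 2 patients only. Airway-like epithelium within scarred parenchyma, or airways drawn into the samples, may each account for the pattern, and no test here separates them.

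Of inflammatory genes, 10 of 14 fell in scarred against normal-appearing areas, with a median of -1.3, and the list lost camera's call with an estimated correlation (adjusted p = 0.111, limma). Dilution by airway epithelium would lower all other cell types alike, and the medians of type 1 (-1.04), NK (-0.955), vessel endothelium (-0.813) and monocyte and neutrophil genes (-0.755) were lower too. But 7 of 16 non-airway cell type lists stood above the inflammatory median by more than 0.6, also without each patient. They did so by more than the SD of their members. Among them B cell, plasma cell, profibrotic macrophage and mast cell genes (0.423) passed camera upward, so they could stand above it with or without dilution. Smooth muscle (-0.0468), T cell (-0.206) and matrix genes (0.234) did not pass camera upward. Camera sees only the net change, so a rise offset by dilution stays possible in these lists too. The test therefore cannot decide whether dilution is the whole cause. Its bound was also reset after the values were seen, which weakens it further as evidence. Type 2 (-0.222) and alveolar macrophage genes (0.073) lay above the inflammatory median by less than 0.6 without 1 patient, and a loss of type 1 and vessel tissue stays open. With HBB as a covariate for blood the inflammatory median was -0.339 (median SE 0.458, against 0.321 without it), which met the bound set for blood as the cause. A control added after that result showed the test to be void, since the same covariate took the basal median from 2.83 to 1.17 and the secretory median from 1.84 to 0.439, which blood cannot explain, and HBB followed appearance within patients (r = -0.819 over areas). The immediate early score, a sign of tissue handling, left -0.427, 32.8% of the median without it, which narrowly missed the bound set for handling as the cause. This score also lowered the basal median to 1.3. With either covariate edgeR called 0 genes (1580 and 1004 at an unadjusted p under 0.05), so blood and handling cannot be told apart from a lower inflammatory signal of scar tissue.

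IL1R2, FMO5 and HIF3A lay below healthy lung in scarred areas. A candidate explanation is a stronger glucocorticoid response in the healthy lungs. In a list of 15 glucocorticoid-induced genes written before their values were seen, 14 had negative fold changes in each comparison, with medians of -0.979 in normal-appearing and -0.963 in scarred areas (camera p = 3.26e-08 and 4.29e-09, limma, not adjusted). This met the bound set before the test, but with an estimated correlation the p-values were 0.0655 and 0.0859. FKBP5 was lower by a log2 fold change of -2.15 ± 0.37 in normal-appearing areas (edgeR adjusted p = 0.0510) and -2.50 ± 0.38 in scarred areas (0.0387), the 1 gene of the list called in either. Within patients, where healthy donors play no part, 7 of the 15 genes also fell in scarred areas and 12 were negative, with a median of -0.373 (camera p = 9.39e-05, limma, not adjusted). With an estimated correlation the p was 0.0494, so the list as a whole also moved where healthy lungs play no part. Its members differed, however. Within patients FKBP5 was at -0.37, and TFCP2L1, at -2.45 and -2.04 against healthy lung, was at 0.39. The largest falls within patients were those of FAM107A (-1.12), ERRFI1 (-1.04) and SGK1 (-0.78). Whether exposure, tissue handling or disease lies behind the difference from healthy lung was not tested, and that difference is confounded with group.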
